A study of Mus musculus and Homo sapiens with 38 samples.

How the data were processed

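RNA was sequenced in 10 mouse libraries of cultured macrophages and of colon cells. Of these, 6 came from bone marrow-derived macrophages (BMM) kept unstimulated or given lipopolysaccharide (LPS), and 4 from colon lamina propria mononuclear cells (LPM) of germ-free (GF) or conventionally raised (CR) mice. Wild-type and Il10-/- mice gave libraries in both systems. The series holds 38 samples; the other 28 are 24 mouse and 4 human libraries of open chromatin (FAIRE-seq), for which no processed values were available, and they are not analysed here.

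The authors deposited 1 matrix of RPKM values (reads scaled by gene length and library depth) with 23893 gene symbols and 10 columns, 1 per RNA library. Reads had been mapped with GSNAP to the mouse assembly mm9, per the submitters' processing notes. The read counter, the gene annotation and the treatment of reads that map to several places are not given in the sources used here. The matrix has no coordinates and the reference gene table at hand belongs to another assembly, so no positions are printed. No symbol was duplicated, and 93.4% of the symbols were found in the reference gene table.

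Library depth and a length per gene were worked out from the steps between RPKM values, and the values were turned back into whole reads. For each gene the smallest length from 20 to 120000 bases was taken at which every value was whole, within 0.0002 reads plus a small relative allowance. All 179466 values above 0, from 22192 genes, then gave whole reads. Because the length was chosen for this, that share is partly built in, and reads can be too few by a common factor. The depths so found ran from 56.5 to 105.1 M (mega) reads in the BMM libraries and from 6.0 to 13.0 M reads in the LPM libraries. A value of 3 reads on 1 kilobase corresponds to 0.029 to 0.053 RPKM in BMM and to 0.231 to 0.499 RPKM in LPM. Folds between single libraries carry a 95% exact (Clopper-Pearson) interval from these reads. Such intervals cover counting error only, because reads without molecular identifiers are not independent molecules.

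Groups were taken from the sample titles and the matrix columns. The genotype field of the 2 wild-type LPS BMM libraries reads Il10-/- and contradicts both; under that field there would be no wild-type LPS library. No value was rescaled for the reported results. BMM values were analysed as log2(RPKM + 1) with limma 3.58.1 (trended prior variance) in R 4.3.3, over the 12062 genes with at least 1 RPKM in at least 1 of the 6 BMM libraries. The model had 4 group means. Only the wild-type groups have replicates, so the residual spread has 2 degrees of freedom (prior degrees of freedom 4.1), and the single Il10-/- libraries are assumed to vary like the wild-type ones. Calls used a Benjamini-Hochberg adjusted p under 0.05. All log2 differences are of RPKM + 1, as LPS minus unstimulated, CR minus GF or Il10-/- minus wild-type.

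The LPS response of Il10-/- BMM and all LPM comparisons rest on 1 library per group and were not tested. For these, genes with a log2 difference of at least 1 in size were counted, for LPM among the 14853 genes with at least 1 RPKM in at least 1 of the 4 LPM libraries. A total of 33 gene lists (processes and cell type markers) were fixed before the data were examined, as were the comparisons, the tests and the rule for naming genes. In BMM, the 26 lists with at least 3 tested members were tested with camera of limma at a preset inter-gene correlation of 0.01. There were 130 pairs of list and comparison, adjusted over the lists of each comparison. With a preset correlation, camera judges a list by the spread of statistics across genes. Its p-values therefore do not measure how a list varies between libraries. In LPM, the median log2 difference of each list was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins, giving 132 pairs; this percentile is a description and not a p-value.

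Genes were named by rule. For tested comparisons these are the 10 highest and 10 lowest log2 differences among called genes with a mean of at least 5 RPKM in the higher group and no overlap between the libraries of the groups. For untested comparisons they are the 8 highest and 8 lowest among genes with at least 5 RPKM in the higher library. Predicted genes and symbols starting with Mir or Snor, or with Rn or Rnu and a digit, were passed over. Il10 was followed in every library, and members of the fixed lists serve as examples of their list. The rule set in advance takes as examples the members with the largest differences; some examples in the text were instead chosen for their known roles after the values were seen. Some genes that the rule selects are not reported here.

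The pipeline was tested on simulated data. With 2-fold and 4-fold changes put into counts simulated from the BMM libraries (11428 genes, dispersion 0.0021), between 91% and 100% of the changed genes were called. The share of false calls was between 7.1% and 13.7%, above the nominal level. The simulation started from unstimulated wild-type means, changed 200 genes per effect and used 1 dispersion for all genes and both genotypes. It therefore does not give the share of false calls in the reported comparisons, where the spread of Il10-/- libraries is unknown. A simulated 2-fold change came back as a log2 difference of 0.87 to 0.9. In LPM libraries simulated with counting noise alone, at the depths of the wild-type GF and CR libraries, 1.56% of unchanged genes differed at least 2-fold. The other LPM comparisons were not simulated.

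Alternatives fixed in advance were pseudocounts of 0.1 and 5, other expression filters, rescaling to a common total, median-of-ratios scaling, quantile normalization, no variance trend, a fit with all 10 libraries, a fit of the wild-type BMM libraries alone, a pooled-spread test of the Il10-/- LPS response, a replicate block, the omission of each wild-type library in turn, and an estimated correlation for the list test. Added after seeing the data were limma voom on the recovered reads, a crossed pairing of replicate numbers, and counts limited to genes called and changed at least 2-fold on both the deposited and the median-of-ratios scale. Computations outside limma used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.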

Results

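Gene expression was measured by RNA sequencing in cultured macrophages and in colon lamina propria cells of C57BL/6 mice. The groups differed in Il10 genotype and in exposure to bacteria or a bacterial product. BMM were grown from bone marrow and were either unstimulated or treated for 4 h with 100 ng/mL of LPS, a cell wall component of Gram-negative bacteria. Wild-type BMM gave 2 unstimulated and 2 LPS libraries, and Il10-/- BMM, from mice made deficient in the anti-inflammatory cytokine interleukin-10, gave 1 library in each state. LPM were mononuclear cells of the colon lamina propria selected with beads for CD11b, a surface protein of myeloid cells, with 1 library each from wild-type GF, wild-type CR, Il10-/- GF and Il10-/- CR mice. Depth was 66.8 and 89.0 M reads in unstimulated wild-type BMM, 105.1 and 56.5 M in LPS-treated wild-type BMM, and 84.7 and 69.4 M in unstimulated and LPS-treated Il10-/- BMM. The LPM libraries were shallower, at 13.0 (wild-type GF), 6.0 (wild-type CR), 6.3 (Il10-/- GF) and 7.1 (Il10-/- CR) M reads. Wild-type replicates differed by more than sampling noise, with a chi-square per degree of freedom of 46.8 for the unstimulated and 21.9 for the LPS pair.

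Il10 RNA was found in all 10 libraries, those labelled Il10-/- included. In wild-type BMM it stood at 5.34 and 4.07 RPKM without stimulation and at 84.0 and 93.9 RPKM after LPS. The Il10-/- BMM libraries held 30.8 RPKM without stimulation and 23.5 RPKM after LPS. In LPM it stood at 55.0 RPKM (wild-type GF), 24.0 (wild-type CR), 24.5 (Il10-/- GF) and 50.7 (Il10-/- CR). A value per gene does not show which part of the gene the reads cover, so these levels do not test the targeted allele. The genotype field of the 2 LPS-treated wild-type BMM libraries reads Il10-/-, against their titles, which were followed here. Ctse, Ly6a and Ly6c1 stood at means of 0.365, 4.51 and 1.80 RPKM in these libraries, at 0.534, 1.60 and 0.985 RPKM in unstimulated wild-type, and at 50.5, 675 and 76.3 RPKM in unstimulated Il10-/- BMM.

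The wild-type BMM libraries show how macrophages respond to 4 h of LPS. Cxcl10, a chemokine that attracts T cells, rose from 10.1 ± 1.63 to 6960 ± 146 RPKM (mean ± SD, n = 2), with a log2 difference of 9.30 (limma adjusted p = 1.75e-07). Ccl5, another chemokine, rose from 9.16 ± 0.0834 to 4300 ± 35.0 RPKM, and Irg1, the enzyme that makes itaconate, from 3.71 ± 0.799 to 1930 ± 2.74 RPKM. Il6 rose by 8.11, Il27 by 8.35, Il1b by 7.91 and the prostaglandin synthase gene Ptgs2 by 8.10 on the log2 scale. Gbp5 (8.43), Cd69 (8.17) and the antiviral gene Rsad2 (8.04) complete the 10 largest increases. Cd300lb, an activating receptor of myeloid cells, fell from 132 ± 2.48 to 0.933 ± 0.197 RPKM (log2 difference -6.11, limma adjusted p = 2.96e-07). The myeloid transcription factor genes Cebpa (-4.84) and Lyl1 (-4.16) and the chemokine receptor gene Cxcr4 (-4.60) fell as well, with Sesn1, Lhfpl2, Arhgap25 and Tmem86a between -4.85 and -4.24.

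The inflammatory lists rose together in wild-type BMM after LPS. Chemokines rose in 18 of 18 members, inflammatory cytokines in 17 of 17, interferon-stimulated genes in 33 of 33, and NF-kB members and feedback inhibitors in 26 of 26, with the same counts when adjusted over the list alone. The median log2 differences of these lists were 5.22, 3.87, 4.56 and 2.82, with camera adjusted p of 3.41e-19, 6.90e-18, 8.21e-32 and 4.35e-24 (limma). Tnf, a central inflammatory cytokine, rose from 19.2 ± 3.31 to 1330 ± 195 RPKM, and Nfkbia, the inhibitor of NF-kB, from 43.4 ± 15.9 to 759 ± 79.8 RPKM. Of the 12 IL-10 target genes, 10 rose and 2 fell (10 and 2 adjusted over the list alone; camera adjusted p = 2.54e-09), among them Socs3 by 7.85, a feedback inhibitor of cytokine receptors. MHC class I presentation genes rose in 11 of 14 members (11 adjusted over the list alone; camera adjusted p = 3.23e-10). With an estimated correlation each of these 6 lists has an adjusted p = 0.285. That setting tests each list on the 2 residual degrees of freedom of the fit, so it has little power in these data. The preset correlation uses the spread across genes, so its small p-values do not measure variation between libraries. Cell cycle genes fell in 19 of 20 members (19 adjusted over the list alone), though camera did not separate them from other genes (adjusted p = 0.183). It did so with median-of-ratios scaling (adjusted p = 1.97e-02) and with the replicate block (adjusted p = 4.21e-02), but not with an estimated correlation (adjusted p = 0.844). Under median-of-ratios scaling 12 of the 20 fell, and the respiratory chain list turned from 13 of 13 lower to 5 higher and 1 lower.

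In total 10391 of 12062 genes changed in wild-type BMM after LPS, 2071 upward and 8320 downward (limma, Benjamini-Hochberg adjusted p under 0.05). The median of all genes lay at -0.60 on the log2 scale, so the split depends on scaling: with median-of-ratios scaling 4114 genes rose and 4112 fell. Genes called and changed at least 2-fold on both scales numbered 1846, of which 1043 rose and 803 fell. With the replicate block the count was 10210.

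**Figure D1:**
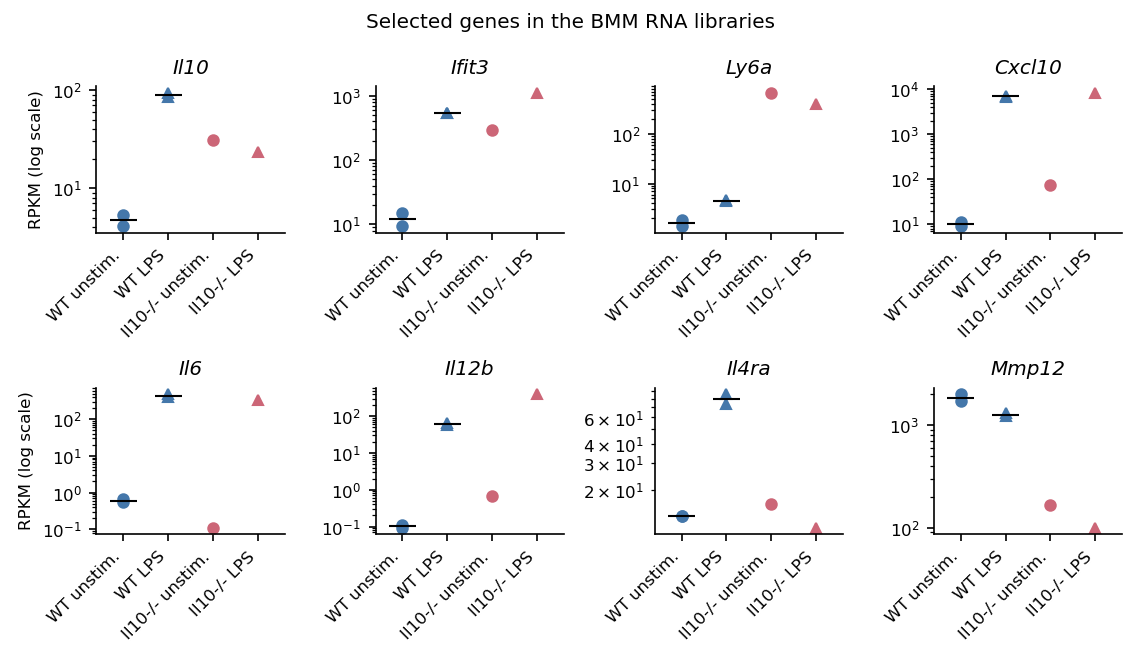
RPKM on a log scale of 8 genes in the 6 BMM libraries; circles are unstimulated and triangles LPS-treated libraries, blue is wild-type and red Il10-/-, and the black bar is the mean of the wild-type pair. Ly6a reached 675 and 391 RPKM in the Il10-/- libraries against means of 1.60 and 4.51 RPKM in wild-type, and Il12b after LPS reached 398 RPKM against a wild-type mean of 60.8.

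The Il10-/- BMM pair gives the LPS response of cells labelled Il10-/-, with 1 library per state and no test. The largest increases included inflammatory genes: Ptgs2 went from 0.565 to 724 RPKM (1280-fold, counting interval 1110 to 1480), and Il6 from 0.109 to 342 RPKM (3130-fold, interval 1700 to 6540). Ptgs2 had the largest log2 difference (8.85), followed by the neutrophil chemoattractant Cxcl1 (8.42), Il6 (8.27), Irg1 (8.01), Il12b, which encodes a subunit of IL-12 and IL-23 (7.89), Il27 (7.81), Cd69 (7.69) and Il1a (7.67). Lower after LPS were Cd300lb (-6.21), Cxcr4 (-5.00), Zfp36l2 (-4.99), Tmem86a (-4.98), Sesn1 (-4.98), Lpar6 (-4.83) and Rab3il1 (-4.83). At least 2-fold higher were 17 of 18 chemokines, 15 of 17 inflammatory cytokines, 20 of 26 NF-kB genes and 23 of 33 interferon-stimulated genes, and 18, 16, 25 and 31 with median-of-ratios scaling. Of the 1043 genes that rose at least 2-fold in wild-type on both scales, 1027 (98.5%) were higher after LPS in Il10-/- and 756 (72.5%) at least 2-fold so, with medians of 1.92 in wild-type and 1.54 in Il10-/-. Of the 803 that fell, 802 (99.9%) were lower in Il10-/- and 773 (96.3%) at least 2-fold so. The falling genes had medians of -1.89 in wild-type and -2.10 in Il10-/-. These 2-fold shares depend on scaling: with median-of-ratios scaling of the Il10-/- libraries they were 998 (95.7%) of the rising and 619 (77.1%) of the falling genes, with the same direction in 1042 and 794. Across 12062 genes the responses of the genotypes correlated with a Pearson r of 0.92 and a Spearman rho of 0.90; genes are not independent replicates, so no p is given. In all 886 genes were at least 2-fold higher and 4363 lower, which median-of-ratios scaling turned to 2042 and 1136.

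Unstimulated Il10-/- BMM were compared with unstimulated wild-type BMM. Interferon-stimulated genes were higher in the Il10-/- library in 33 of 33 members (33 adjusted over the list alone), with a median log2 difference of 2.46. The camera adjusted p was 1.21e-24 (limma), and 0.462 with an estimated correlation. The smaller p rests on the spread across genes and cannot stand in for replicate Il10-/- libraries. Ifit3, an interferon-induced antiviral gene, stood at 12.0 ± 3.84 RPKM in wild-type (n = 2) and 291 RPKM in Il10-/- (log2 difference 4.52, limma adjusted p = 1.30e-04). Irf7, a transcription factor of the interferon response, stood at 29.3 ± 8.57 and 537 RPKM, and Isg15, an interferon-induced ubiquitin-like protein, at 21.4 ± 6.86 and 209 RPKM. The largest difference was in Ly6a, a surface antigen of stem and activated cells, at 1.60 ± 0.322 RPKM in wild-type and 675 RPKM in Il10-/- (log2 difference 8.03, limma adjusted p = 8.37e-06). Other genes of the Ly6 and Schlafen families followed, with Ly6c1 at 5.29, Slfn1 at 5.24, Ly6i at 4.52 and Slfn4 at 4.34. Ms4a4c (5.38), the protease gene Ctse (5.07), Ifi44 (4.27) and Ifit2 (4.23) complete the 10 highest.

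Antigen presentation and monocyte genes were also higher in the unstimulated Il10-/- library. MHC class II genes rose in 9 of 10 members (9 adjusted over the list alone; median 1.04; camera adjusted p = 3.58e-05), with H2-Ab1 at 216 ± 48.6 RPKM in wild-type and 789 RPKM in Il10-/-. MHC class I genes rose in 12 of 14 (12 adjusted over the list alone; camera adjusted p = 1.00e-07), monocyte markers in 7 of 8, with 1 lower (7 and 1 adjusted over the list alone; camera adjusted p = 1.71e-04) and neutrophil markers in 10 of 12, with 1 lower (10 and 1 adjusted over the list alone; camera adjusted p = 1.14e-04). Ccr2, the receptor that draws monocytes to tissue, stood at 40.6 ± 3.07 and 198 RPKM, and S100a9, abundant in neutrophils and monocytes, at 155 ± 21.5 and 501 RPKM. Pattern-recognition receptors rose in 12 of 21 members and fell in 1 (12 and 1 adjusted over the list alone; camera adjusted p = 4.22e-05), with Tlr9, a sensor of bacterial DNA, at 5.13 ± 0.532 and 46.3 RPKM. Resident macrophage markers rose in 7 of 13 (9 adjusted over the list alone; camera adjusted p = 1.17e-04). With an estimated correlation each of these 6 lists has an adjusted p = 0.462.

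Lower in the unstimulated Il10-/- library were cell cycle genes (13 of 20; 13 adjusted over the list alone; camera adjusted p = 3.34e-04) and cholesterol synthesis genes (13 of 16; 13 adjusted over the list alone; camera adjusted p = 8.07e-05). With an estimated correlation these have an adjusted p = 0.613 and an adjusted p = 0.593. The metal-binding gene Mt2 stood at 45.3 ± 0.610 RPKM in wild-type and 2.93 RPKM in Il10-/- (log2 difference -3.56, limma adjusted p = 2.25e-05). Mmp12, the macrophage elastase, stood at 1860 ± 213 and 168 RPKM (log2 difference -3.45), and the monocyte chemoattractants Ccl2 and Ccl7 were lower by log2 differences of -3.21 and -2.92. Fabp4, a fatty acid carrier, Vsig8, Cxcl14, Ppic, Atp6v0d2 and the gelatinase gene Mmp9 lay between -3.00 and -2.53. In total 5328 genes differed, 2182 higher and 3146 lower in Il10-/- (limma), and 2768 higher and 2363 lower with median-of-ratios scaling. When rescaled to a common total, 2584 were higher and 2116 lower. That total lay above the sum of every library, so the pseudocount of 1 also weighed less there. At least 2-fold on both scales differed 607 genes higher and 245 lower. The count was 3978 with the replicate block. The test takes the single Il10-/- library to vary like the wild-type ones, and 1 library cannot separate genotype from culture.

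**Figure D2:**
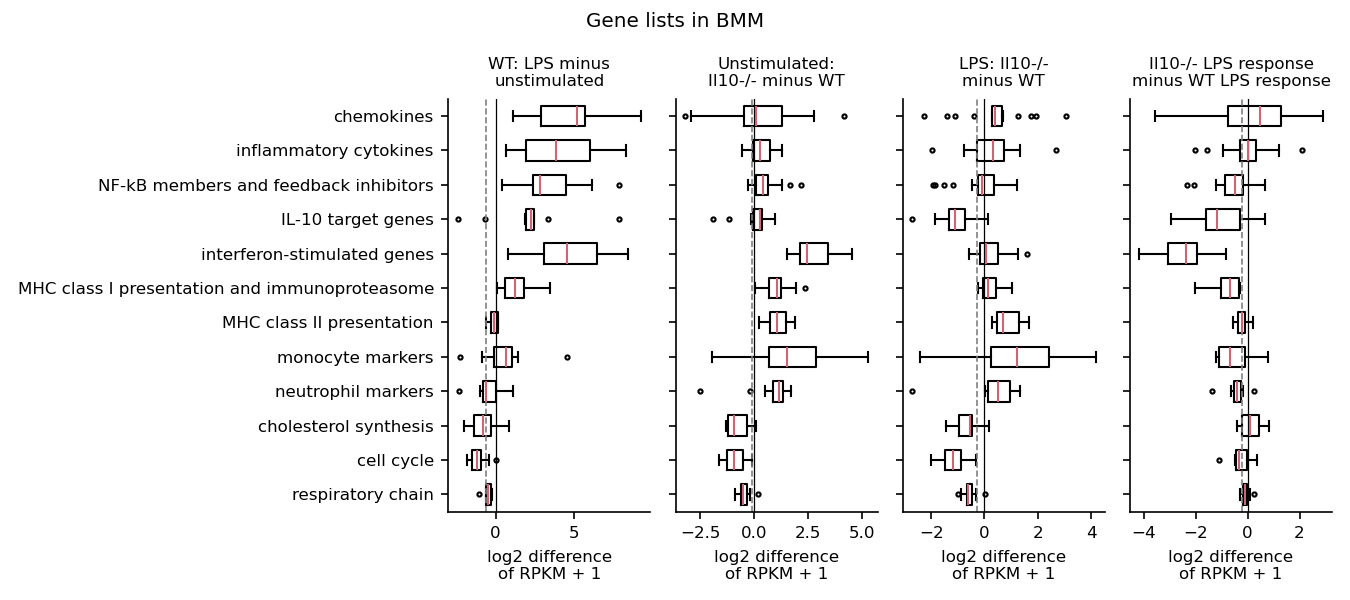
Box plots of the log2 differences of RPKM + 1 of the members of 12 gene lists in 4 BMM comparisons; boxes span the quartiles, red lines are medians, whiskers reach 1.5 times the box length, and the dashed grey line is the median of all genes. Interferon-stimulated genes had medians of 4.56 in the wild-type LPS response, 2.46 for Il10-/- minus wild-type without stimulation, 0.05 after LPS and -2.39 in the difference of the LPS responses.

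After LPS, Il10-/- and wild-type BMM were compared in the same way. IL-10 target genes were lower in the Il10-/- library in 10 of 12 members (10 adjusted over the list alone), with a median log2 difference of -1.09 and a camera adjusted p of 6.42e-03 (limma; adjusted p = 0.529 with an estimated correlation). Under median-of-ratios scaling 8 were lower and 1 higher. Without stimulation 5 of the 12 were higher in Il10-/- and 2 lower (6 and 2 adjusted over the list alone), with a median of 0.26 and no camera call (adjusted p = 0.155). Il4ra, the receptor for IL-4 and IL-13, stood at 79.5 ± 8.39 RPKM in wild-type (n = 2) and 11.2 RPKM in Il10-/- (log2 difference -2.71, limma adjusted p = 1.53e-04). Il1rn, the IL-1 receptor antagonist, stood at 605 ± 44.1 and 223 RPKM, Socs3 at 465 ± 40.0 and 204 RPKM, and Nfil3, an IL-10-induced transcription factor, at 25.8 ± 0.672 and 10.0 RPKM. Socs3, Tnip3 and Zfp36 of this list are also on the NF-kB list.

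Inflammatory cytokine genes differed in both directions after LPS, more of them upward. Il12b stood at 60.8 ± 5.86 RPKM in wild-type and 398 RPKM in Il10-/- (log2 difference 2.69, limma adjusted p = 1.53e-04), and the neutrophil chemoattractant Cxcl1 at 101 ± 51.6 and 788 RPKM (3.05). Of the 17 inflammatory cytokines 6 rose and 2 fell (6 and 2 adjusted over the list alone; 10 and 2 with median-of-ratios scaling; camera adjusted p = 1.61e-03; adjusted p = 0.631 with an estimated correlation). Il23a rose by 0.77, Il18 by 0.79 and Tnf by 0.73, while Il19, a relative of Il10, fell by 1.96 on the log2 scale. Il6, at 442 ± 55.4 and 342 RPKM, and Il1b, at 1810 ± 276 and 1470 RPKM, did not pass. Chemokines rose in 7 of 18 members and fell in 3, Ccl2, Ccl7 and Ccl8 (7 and 3 adjusted over the list alone; 13 and 3 with median-of-ratios scaling; camera adjusted p = 2.75e-04; adjusted p = 0.529 with an estimated correlation). MHC class II genes were higher in 9 of 10 members (9 adjusted over the list alone; camera adjusted p = 6.05e-07; adjusted p = 0.529 with an estimated correlation).

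The genes that differed most after LPS were partly those that differed without it. Monocyte and neutrophil markers also had list medians above those of all genes after LPS, at 1.22 and 0.50 against -0.29. Higher in Il10-/- were Ly6a (6.15), the small Cajal body RNA Scarna17 (4.34), Ctse (4.22), Ly6c1 (4.17), Ly6i (3.54), Gpr141 (3.21), Ccr2 (3.06), Mefv (2.97) and P2ry13 (2.87). Lower were Mt2 (-4.09), Mmp12 (-3.65), Rnd1 (-3.52), Cebpb, a transcription factor of inflammatory genes (-3.16), Sema4c (-3.09), Nek6 (-2.77), Timp1, an inhibitor of matrix proteases (-2.77), Mt1 (-2.73) and Mmp9 (-2.71). Cell cycle genes were lower in 18 of 20 members (18 adjusted over the list alone; camera adjusted p = 4.28e-03; adjusted p = 0.644 with an estimated correlation). In total 6692 genes differed, 1369 higher and 5323 lower (limma), and 3016 higher and 2620 lower with median-of-ratios scaling; at least 2-fold on both scales were 349 higher and 313 lower. The single Il10-/- library is again taken to vary like the wild-type ones. Without wild-type LPS replicate 2 the count was 4208, and with the replicate block 5334. Across genes the Il10-/- to wild-type differences without and with LPS correlated with a Pearson r of 0.72 and a Spearman rho of 0.72.

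The difference between the LPS responses of the genotypes was tested as an interaction. Interferon-stimulated genes gained less from LPS in Il10-/- BMM: 32 of 33 passed with a smaller response (33 adjusted over the list alone), with a median of -2.39 and a camera adjusted p of 3.51e-24 (limma; adjusted p = 0.94 with an estimated correlation). Ifit2 went from 9.82 ± 1.85 to 1520 ± 173 RPKM in wild-type and from 200 to 1570 RPKM in Il10-/- (interaction -4.17, limma adjusted p = 1.53e-03). After LPS itself 9 of the 33 were higher in Il10-/-, 2 lower and 22 not called; under median-of-ratios scaling 17 were higher and 0 lower. Against other genes the list was higher in Il10-/- after LPS (camera adjusted p = 1.71e-04; adjusted p = 0.631 with an estimated correlation). IL-10 target genes had a smaller response in 8 of 12 members (8 adjusted over the list alone; camera adjusted p = 5.82e-04) and MHC class I genes in 6 of 14 (8 adjusted over the list alone; camera adjusted p = 4.26e-04). With an estimated correlation both have an adjusted p = 0.94. Chemokines passed upward in 4 of 18 members and downward in 3 (7 and 4 adjusted over the list alone; camera adjusted p = 1.79e-03; adjusted p = 0.94 with an estimated correlation; 0.07 with median-of-ratios scaling).

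Il10 itself rose with LPS in wild-type (log2 difference 3.99, limma adjusted p = 2.00e-06) and had an interaction of -4.37. Saa3, an acute-phase protein gene, had the largest negative interaction (-4.94); those below Il10 and Ifit2 in size were Rnd1 (-3.75), Ifit1 (-3.58), Ccl5 (-3.57), Iigp1 (-3.48), Ifit3 (-3.48), Pydc3 (-3.41) and Mx1 (-3.41). The largest positive ones were in Gdf15, a stress-induced cytokine (2.97), the growth arrest gene Gadd45a (2.92), Bhlhe40 (2.22), Plat (2.19), the phosphatase genes Dusp5 (2.14) and Dusp4 (2.09), Il12b (2.08), Clcf1 (2.04), Eno2 (2.02) and Rapgef5 (1.92). Gadd45a fell from 26.5 ± 0.0171 to 2.49 ± 0.340 RPKM in wild-type and stood at 8.32 and 7.93 RPKM in Il10-/-. In total 1134 genes passed, 200 positive and 934 negative (limma), and 555 positive and 525 negative with median-of-ratios scaling; at least 2-fold on both scales were 83 and 216. This count depends on single libraries: it was 353 without wild-type LPS replicate 1, 423 without wild-type LPS replicate 2 and 2141 without wild-type unstimulated replicate 2. With the replicate block it was 746, and with the crossed replicate block 1916.

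**Figure D3:**
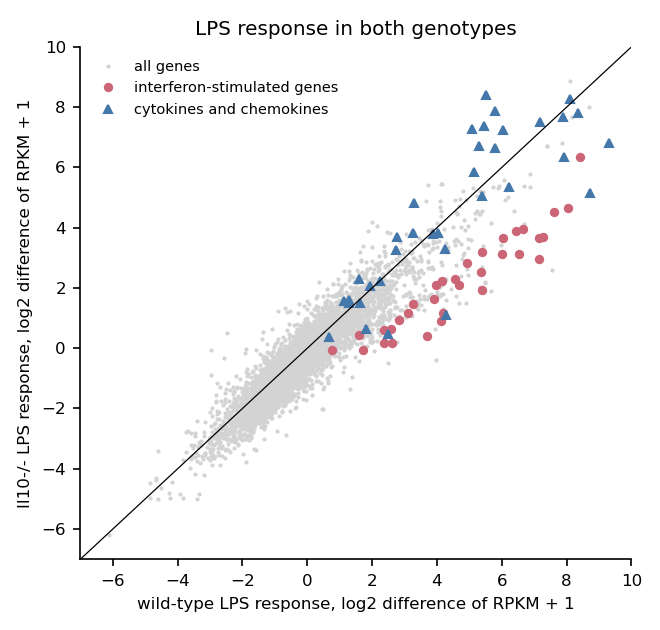
Log2 differences of RPKM + 1 between LPS-treated and unstimulated BMM, wild-type on the horizontal and Il10-/- on the vertical axis, for all 12062 genes (grey), interferon-stimulated genes (red) and cytokine and chemokine genes (blue), with the line of equal response. All 33 interferon-stimulated genes lie below the line, while of 35 cytokine and chemokine genes 15 lie below and 20 above it.

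Averaged over both states, 2 Il10-/- libraries were set against 4 wild-type libraries. Ly6a (7.09, limma adjusted p = 2.13e-06), Ly6c1 (4.73), Ctse (4.65), Scarna17 (4.25), Ly6i (4.03), Ms4a4c (3.87), Slfn1 (3.59), Slfn4 (3.41), Ly6e (3.24) and Gpr141 (3.02) were higher in Il10-/- in both states. Mt2 (-3.83, limma adjusted p = 4.49e-06), Mmp12 (-3.55), Ccl2 (-2.74), Vsig8 (-2.70), Mmp9 (-2.62), Fabp4 (-2.61), Mfge8, which helps to clear dying cells (-2.60), Atp6v0d2 (-2.57), Hbegf (-2.46) and Cxcl14 (-2.44) were lower in both. Interferon-stimulated genes were higher in 33 of 33 members (33 adjusted over the list alone; camera adjusted p = 8.40e-22), MHC class II genes in 10 of 10 (10 adjusted over the list alone; camera adjusted p = 1.60e-06) and MHC class I genes in 12 of 14 (12 adjusted over the list alone; camera adjusted p = 2.67e-07). After LPS alone 5 of the 14 MHC class I genes were called higher (4 adjusted over the list alone; 8 with median-of-ratios scaling), with a median of 0.11. With an estimated correlation each of the 3 lists has an adjusted p = 0.375 over both states. Cell cycle genes were lower in 18 of 20 (18 adjusted over the list alone; camera adjusted p = 1.18e-03) and cholesterol synthesis genes in 14 of 16 (14 adjusted over the list alone; camera adjusted p = 1.39e-03); with an estimated correlation both have an adjusted p = 0.623. In total 7702 genes differed, 2226 higher and 5476 lower (limma), and 3676 higher and 3388 lower with median-of-ratios scaling; at least 2-fold on both scales were 431 and 219. With the replicate block the count was 6213. Over the 130 pairs of list and comparison in BMM, camera called 68; with an estimated correlation it called 0, with 6 at an unadjusted p under 0.05.

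The wild-type lamina propria libraries of CR and GF mice were compared, with 1 library per group, no test, and intervals for counting error only. Colonization cannot be separated here from mouse, preparation and the sex-linked RNA. Epithelial markers were at least 2-fold higher in the CR library in 17 of 17 members, with a median log2 difference of 2.69. Muc2, the main colonic mucin, stood at 8.92 RPKM in GF and 103 RPKM in CR (11.6-fold, interval 10.7 to 12.5), and Krt18, an epithelial keratin, at 13.5 and 125 RPKM. Endothelial markers were lower in 9 of 9 members (median -1.68), with Cdh5, the adhesion protein of vessel junctions, at 94.1 and 28.4 RPKM. Mast cell markers were lower in 7 of 8 members (median -2.43), with the mast cell protease Mcpt4 at 32.3 and 3.54 RPKM. Among myeloid lists, monocyte markers were higher in 7 of 8 members (median 0.77) and resident macrophage markers lower in 13 of 15 (median -0.59), with C1qa, a complement subunit, at 227 and 93.0 RPKM. Chemokines were lower in 15 of 19 members (median -0.53) and interferon-stimulated genes in 28 of 33 (median -0.52), with Ccl8 at 224 and 46.1 RPKM. The medians of these lists lay outside the central 95% of random lists.

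Cyp2c55, a cytochrome P450 of the intestinal epithelium, had the highest difference between the wild-type libraries, at 1.32 RPKM in GF and 190 RPKM in CR (144-fold, interval 103 to 208). The secreted epithelial genes Guca2a (4.03), Reg4 (3.56) and Reg3b, an antimicrobial lectin listed at 0 in GF and at 13.2 RPKM in CR, were higher too, with B4galnt2 (3.90) and Apol10a (3.56). Lower in CR were Gpihbp1 (-2.97), the granulocyte growth factor Csf3 (-2.93), Mcpt4 (-2.87), Fmod (-2.71), Scgb3a1 (6.69 RPKM in GF, listed at 0 in CR) and the IgE receptor gene Fcer1a (5.35 RPKM in GF, listed at 0 in CR). The GF library also differed from the other 9 in sex-linked RNA: Xist, expressed from the inactive X chromosome, stood at 31.0 RPKM there and at no more than 0.00928 RPKM in the other LPM libraries. The Y-linked genes Ddx3y and Eif2s3y stood at 0.0166 and 0 RPKM in it and at 20.2 and 38.2 RPKM in the CR library, and Tsix at 15.0 and 0 RPKM. Any comparison with the wild-type GF library thus also compares libraries that differ in these RNAs. In total 1105 genes were at least 2-fold higher and 650 lower in CR, against 1026 and 665 with median-of-ratios scaling. Rescaling to a common total gave 1767 and 777. That total lay above the sums of the LPM libraries (313531 to 366874 RPKM), so the pseudocount of 1 weighed less. The latter counts thus do not show the effect of scaling alone, here and in the other LPM comparisons. For 85.2% of the 1755 genes the counting interval excludes no difference.

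In Il10-/- LPM, the CR library held more RNA of lymphocyte genes than the GF library. B cell and plasma cell markers were higher in 11 of 11 members (median log2 difference 2.25) and T cell markers in 12 of 12 (median 1.57). Mzb1, a chaperone of antibody secretion, stood at 6.81 RPKM in GF and 221 RPKM in CR (32.5-fold, interval 23.6 to 45.9), and Cd3g, a T cell receptor subunit, at 2.02 and 10.7 RPKM. MHC class II genes were higher in 8 of 10 members (median 1.15), MHC class I genes in 13 of 14 (median 0.72), chemokines in 12 of 19 (median 0.75), inflammatory cytokines in 12 of 17 (median 0.64), NF-kB genes in 21 of 26 (median 0.63) and neutrophil markers in 6 of 7 (median 0.98). Cxcl9, an interferon-induced chemokine, stood at 1.52 and 14.6 RPKM, Il12b at 7.22 and 25.7 RPKM, and S100a9 at 3.33 and 35.3 RPKM (11 and 130 reads). Endothelial markers were lower in 9 of 9 members (median -2.77) and fibroblast and smooth muscle markers in 11 of 11 (median -1.06). Epithelial markers, with a median of -0.23, lay within the central 95% of random lists, unlike the other lists named here. Because markers of several cell types differed, changes within macrophages cannot be told apart here from a different mixture of cells.

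The antimicrobial lectins Reg3b and Reg3g were among the highest differences in Il10-/- LPM, at 0.418 and 50.3 RPKM for Reg3b and at 0 and 17.8 RPKM for Reg3g, with Ly6d (3.49) and the B cell factor Pou2af1 (3.40). Lower in CR were Car1, a colonic epithelial carbonic anhydrase (-5.52), the muscle genes Des (-4.79), Actg2 (-4.64) and Cnn1 (-3.95), and Fabp4 (-3.79), Cdh5 (-3.59), Tm4sf1 (-3.59) and Emcn (-3.49), expressed in vessels. The small structured RNAs Rpph1, Rmrp and Scarna6 also stood out, and they were low in the GF library rather than high in the CR one: Rpph1 stood at 331 RPKM there against 17300 RPKM in Il10-/- CR, 15500 in wild-type CR and 32600 in wild-type GF. In total 888 genes were at least 2-fold higher and 1008 lower in CR, against 862 and 1079 with median-of-ratios scaling. Rescaling to a common total, where the pseudocount weighed less, gave 1309 and 1389. For 82.4% of the 1896 genes the counting interval excludes no difference. Across 14853 genes, the CR minus GF differences of the genotypes correlated with a Pearson r of 0.21 and a Spearman rho of 0.19.

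**Figure D4:**
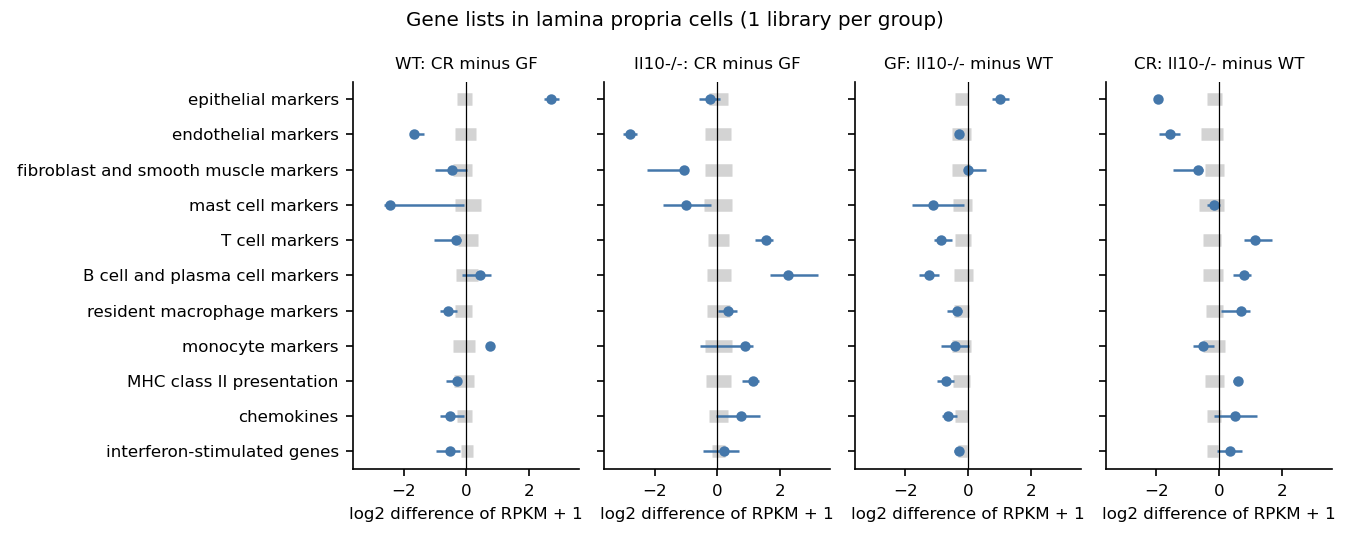
Median log2 difference of RPKM + 1 (dot) and quartiles (line) of 11 gene lists in the 4 comparisons of LPM libraries; grey bars give the central 95% of the medians of random lists of the same size and expression. Epithelial markers lie at 2.69 for CR minus GF in wild-type and at -1.95 for Il10-/- minus wild-type in CR mice, and endothelial markers are below the grey bar in both CR minus GF comparisons.

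Il10-/- and wild-type LPM of GF mice were compared in the absence of bacteria, again with 1 library each. Epithelial markers were higher in Il10-/- in 16 of 17 members (median 1.03), with Car1 at 82.5 RPKM in wild-type and 1240 RPKM in Il10-/- (15.0-fold, interval 14.2 to 15.9). Lower were B cell and plasma cell markers in 11 of 11 members (median -1.24), T cell markers in 12 of 12 (median -0.87), mast cell markers in 6 of 8 (median -1.11), erythroid markers in 4 of 4 (median -1.32), MHC class II genes in 8 of 10 (median -0.72) and chemokines in 18 of 19 (median -0.64). These medians lay outside the central 95% of random lists. The differences in MHC class II and chemokine genes cannot be told apart from a different mixture of cells. The highest differences included the epithelial genes Cyp2c55 (4.17), B4galnt2 (3.31) and Cyp2c65 (3.22), with Chil1 and Pbsn, listed at 0 in wild-type and at 14.0 and 7.32 RPKM in Il10-/-. Lower in Il10-/- were Rpph1 (-6.62), Rmrp (-4.69), Scarna6 (-4.38), Pole2 (-2.92), Inmt (-2.50) and Klhdc1 (-2.43). Eif2s3y, Ddx3y, Xist and Tsix differed as stated for the wild-type GF library. In total 294 genes were at least 2-fold higher and 614 lower, and 396 and 393 with median-of-ratios scaling. Rescaling to a common total, where the pseudocount weighed less, gave 696 and 633. For 67.7% of the genes on the deposited scale the counting interval excludes no difference.

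In CR mice the same genotypes were compared in the presence of bacteria. Epithelial markers were lower in Il10-/- in 17 of 17 members (median -1.95) and endothelial markers in 9 of 9 (median -1.58), with Krt18 at 125 RPKM in wild-type and 28.4 RPKM in Il10-/- (4.39-fold lower, interval 3.84 to 5.03). T cell markers were higher in 11 of 12 members (median 1.14), B cell and plasma cell markers in 11 of 11 (median 0.80), resident macrophage markers in 12 of 15 (median 0.71, while monocyte markers were lower in 6 of 8, median -0.52), MHC class II genes in 10 of 10 (median 0.61), MHC class I genes in 14 of 14 (median 0.58), chemokines in 13 of 19 (median 0.50) and interferon-stimulated genes in 24 of 33 (median 0.34). All these medians lay outside the central 95% of random lists. With cell type markers differing this much, the MHC, chemokine and interferon lists cannot be assigned to changes within macrophages. Ccl8, a chemokine of monocytes and T cells, stood at 46.1 and 245 RPKM (5.31-fold, interval 4.44 to 6.39), and Ctla4, an inhibitory T cell receptor, at 21.0 and 84.2 RPKM. Trat1 (2.77), C6 (2.31), Gbp2b (2.23), Serpina3f (2.03), Ren1 (2.01) and Ren2 (1.98) were the other highest. Lowest were Cyp2c55 (-5.32), Car1 (-4.69), Actg2 (-3.04), Ces2c (-2.97), Fabp4 (-2.91), Des (-2.83), Guca2a (-2.82) and Sycn (-2.82). In total 339 genes were at least 2-fold higher and 1269 lower, and 472 and 911 with median-of-ratios scaling. Rescaling to a common total, where the pseudocount weighed less, gave 562 and 1631. For 80.5% of the genes on the deposited scale the counting interval excludes no difference.

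Across genes, the Il10-/- to wild-type differences in GF and CR mice correlated negatively, with a Pearson r of -0.23 and a Spearman rho of -0.22. Between BMM and LPM, the genotype difference correlated with a Pearson r of 0.12 and a Spearman rho of 0.13 over 11509 genes. The wild-type LPS response of BMM and the wild-type CR minus GF difference of LPM correlated with a Pearson r of -0.12 and a Spearman rho of -0.10. In all, 6 such pairs of comparisons that share no library were examined, and over the 132 pairs of list and comparison in LPM, 72 medians lay outside the central 95% of random lists.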

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

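The results below stood out because a response differed between groups, and the tests of explanations were all chosen after the result was seen. The LPS response differed by genotype in 1134 BMM genes (limma interaction, Benjamini-Hochberg adjusted p under 0.05). The single genes named for this difference had a positive interaction for Gdf15 (2.97), Gadd45a (2.92), Bhlhe40 (2.22), Plat (2.19), Dusp5 (2.14), Dusp4 (2.09), Il12b (2.08), Clcf1 (2.04), Eno2 (2.02) and Rapgef5 (1.92). A positive value can be a weaker fall, as in Gadd45a, Bhlhe40 and Dusp4. The interaction was negative for Saa3 (-4.94), Il10 (-4.37), Ifit2 (-4.17), Rnd1 (-3.75), Ifit1 (-3.58), Ccl5 (-3.57), Iigp1 (-3.48), Ifit3 (-3.48), Pydc3 (-3.41) and Mx1 (-3.41).

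In LPM, the CR minus GF medians of 3 lists had opposite signs in the genotypes and lay outside the central 95% of random lists in both. For chemokines the median difference between genotypes was 0.91, for pattern-recognition receptors and adaptors 0.69 and for T cell markers 2.04. These differences between single libraries were not tested, and they cannot be told apart from differences in the mixture of cells.

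Interferon-stimulated genes were already higher in the unstimulated Il10-/- BMM library. After LPS their median difference was 0.05 on the deposited scale and 0.45 with median-of-ratios scaling. RNA of an LPS-treated culture mixed into that library could do this, but the induced cytokine and chemokine genes imply a median share of 0.633% of such RNA, against 18.4% implied by the interferon-stimulated genes, so this explanation is argued against. A lower share of cells with resident macrophage markers is argued against by that list, with 7 of 13 higher, 0 lower and a median of 0.61. The list does not decide for macrophages as a whole, since the macrophage elastase gene Mmp12 was lower (1860 RPKM in wild-type, 168 in Il10-/-). Scaling is argued against, as 3 rescalings left the median of the list at 2.51 or higher with 33 of 33 members called. The number of genes called lower moved from 3146 to as few as 2116. The 2116 came with the common total, where the pseudocount of 1 weighed less too. Monocyte markers (7 of 8) and neutrophil markers (10 of 12, median 1.16) were higher too, so a change in the composition or maturity of the culture stays open and was not tested. A response to interferon that follows from the genotype and one that belongs to this single culture both remain open.

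In wild-type LPM, the CR library held more epithelial and less endothelial RNA than the GF library. That 17 of 17 epithelial markers were higher, with Car1 at 695 RPKM and Muc2 at 103 RPKM in cells selected for CD11b, restates the pattern, so a larger share of epithelial RNA remains possible and untested. A lower share of macrophages alone would raise endothelial markers too, and would not give their median of -1.68. That median is part of the pattern, so it is no separate test. Resident macrophage markers were lower in 13 of 15 members, so a lower share together with other changes stays open. Differences in cell recovery between the preparations and differences between the mice were not tested.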

How the results depend on the processing

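Limited to genes called and changed at least 2-fold on both scales, a choice made after the data were seen, the BMM counts went to 1846 (wild-type LPS response), 852 (Il10-/- against wild-type, unstimulated), 662 (the same after LPS), 299 (interaction) and 650 (both states). The added fold limit makes these smaller by construction. Leaving out each wild-type library in turn gave 4208 to 7655 genes for Il10-/- against wild-type after LPS, the lowest without wild-type LPS replicate 2. For the interaction it gave 353 (without wild-type LPS replicate 1) to 2141 (without wild-type unstimulated replicate 2), with 423 without wild-type LPS replicate 2; the cause was not tested. By design, fits without an LPS replicate took their spread from the unstimulated pair alone (SD of log2 differences between replicates 0.191). Those without an unstimulated replicate took it from the LPS pair (0.138). With the replicate block the interaction count was 746, and with the crossed replicate block 1916. Deviations of replicate 1 from its group mean correlated negatively between the unstimulated and LPS pairs (Spearman rho -0.25 over 12062 genes). That gives no ground for pairing by replicate number. The causes were not tested further. With no filter 834 genes were called for the interaction, 333 of them among the 1134, and for Il10-/- against wild-type without stimulation 2993 of the 5328 stayed called; the cause was not tested.

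The Il10-/- LPS response held 5249 genes changed at least 2-fold. It held 2175 with a pseudocount of 5, 3178 with median-of-ratios scaling and 2919 with quantile normalization. With limma and the spread pooled from the wild-type libraries, 10004 genes were called, a count with no fold limit. The causes were not tested, apart from the shrinkage that a larger pseudocount brings by construction.

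In LPM, pseudocounts of 0.1 and 5 gave 2849 and 645 genes for CR against GF in wild-type, and 3065 and 611 in Il10-/-. For Il10-/- against wild-type they gave 1841 and 217 in GF and 2714 and 476 in CR mice. A smaller pseudocount widens differences of low values by construction. Rescaling to a common total raised all values before 1 was added, so its counts carry this effect as well. With at least 5 RPKM in at least 1 library, the GF comparison held 591 genes, the filter removing low genes by construction.

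With an estimated correlation, camera called 0 of the 130 BMM pairs of list and comparison, with 6 at an unadjusted p under 0.05. That setting tests on the 2 residual degrees of freedom and has little power, so the 0 does not decide whether the lists differ. How much of the change this explains was not tested. The Spearman rho with at least 5 RPKM was 0.92 for the LPS responses of the genotypes, 0.73 for the genotype difference without and with LPS, -0.27 for that in GF and CR mice and 0.16 for that in BMM and LPM. With a pseudocount of 5 the latter pair were -0.19 and 0.16; the causes were not tested. Of 1558 pairs of named tested gene and setting, 12 lost the call and 0 reversed. Untested genes were counted as moved when the log2 difference lay outside the counting interval of the fold without a pseudocount. Over all 2118 pairs 280 moved, a label used for untested comparisons only. Among them were 95 of 112 for the Il10-/- LPS response and 69 of 112 for Il10-/- against wild-type in GF mice. The reported value can itself lie outside that interval, as for Ptgs2 in the Il10-/- LPS response (log2 difference 8.85, interval 10.12 to 10.53). The counts of moved pairs therefore do not measure dependence on the processing.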

Other observations

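Macrophage transcription factors split after LPS in wild-type BMM, with 8 of 21 higher and 11 lower (8 and 11 adjusted over the list alone; 11 and 9 with median-of-ratios scaling). Irf1, an activator of interferon and inflammatory genes, rose from 18.4 ± 0.473 to 374 ± 4.97 RPKM (limma adjusted p = 4.32e-07), and Batf (3.58), Cebpd (3.39) and Irf8 (3.09) rose as well. Pparg, a regulator of lipid handling (-3.00), and Egr2 (-2.59) fell. After LPS, Cebpb stood at 82.2 ± 8.33 RPKM in wild-type and 8.27 RPKM in Il10-/- (limma adjusted p = 1.53e-04).

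Glycolysis genes were lower in Il10-/- BMM over both states in 11 of 14 members (11 adjusted over the list alone; camera adjusted p = 1.27e-02; adjusted p = 0.623 with an estimated correlation), with Pgam1 at -1.43, Pgk1 at -1.14 and Ldha at -1.13. Inflammatory bowel disease risk genes were higher in 11 of 16 and lower in 1 (11 and 1 adjusted over the list alone; camera adjusted p = 2.71e-05; adjusted p = 0.375 with an estimated correlation). The median difference of the risk genes was 0.57 without stimulation and 0.05 after LPS, against -0.09 and -0.29 for all genes. With median-of-ratios scaling the risk gene medians were 0.59 and 0.44, so the gap between the states depends on scaling. Over both states Nod2, a sensor of bacterial cell wall fragments, was higher by 0.93, Icosl by 1.40, Prdm1 by 0.73 and Il12b by 1.65.

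The test of genes near Il10 was chosen after the result was seen. Of the 100 measured genes nearest to Il10 in gene order, 4 differed at least 1.5-fold in the same direction in all 4 pairs of Il10-/- and wild-type, against 0.36 expected (hypergeometric exact p = 0.00044; neighbouring genes are not independent). They are Dbi, Ctse, Chil1 and Klhl12; Ctse was higher by 5.07 in unstimulated BMM, 4.22 after LPS, 0.85 in GF and 1.04 in CR LPM. The count restates the pattern, so it does not tell whether DNA of another mouse strain carried along with the targeted allele or regulation by IL-10 lies behind it.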
